A study of Mus musculus with 2 samples.

How the data were processed

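RNA was extracted from kidney tissue of a 10 week old female C57BL/6J mouse with the RNeasy Lipid Tissue Mini Kit, per the labels, and polyadenylated RNA was sequenced in 2 libraries of 1 tissue sample with a stated size range of 350 to 450. The labels call the libraries technical replicates 1 and 2, and they form 1 group. Gene and transcript tables on mm10 with annotation release M4 were used, per the text deposited beside them. Names and versions of the aligner and quantifier are not given in the sources used here. That text also lists signal tracks per strand, which were not used here.

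Expected counts, the estimated number of reads per gene or transcript, were deposited without normalization, per the file headers, and posterior mean counts were deposited beside them. TPM values were deposited as counts over effective length scaled to the same sum in each library, per the file headers. FPKM values were deposited too and are proportional to TPM within a library. The share of each transcript in its gene was deposited as a percent. Per the file headers, the bounds of a credibility interval of TPM and lengths in bases were deposited as well; the level of the interval is not given in the sources used here.

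Each library had 43346 gene rows. Another 97 spike-in rows and 26248 numbered short RNA rows were at 0 in both and were left out. Symbols, coordinates and biotypes came from GENCODE M21 on the same assembly, and 42462 rows (98%) matched by identifier. The 884 rows without a symbol held 0.074% and 0.085% of expected counts. Expected counts summed to 28263730 in library 1 and 20720537 in library 2. A count of 0 allows up to 3 counts in a library (one-sided 95% limit), which served as the floor for each ratio against 0. Intervals and floors cover counting error only.

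Levels were given per library and as mean and SD. Agreement was measured across genes at TPM 1 or more in at least 1 library on log2(TPM + 1). For differences between the libraries, expected counts were rounded and library sizes scaled by TMM (edgeR 4.0.16). A quasi-likelihood model could not be fitted with 1 library on each side, so a two-sided exact conditional binomial test was run on genes with at least 10 counts over both libraries (scipy 1.17.1, Python 3.11.15), with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and an absolute log2 ratio of 1 or more, computed with a prior count of 0.5. Each list's median log2 ratio was ranked among 10000 random lists of the same size, drawn from the 200 genes nearest in mean expression to each member.

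GC content came from the most abundant transcript whose length lay within 10% of the reference transcript of the same identifier, which gave a value for 95.5% of genes with at least 100 counts. Kap and Aadat had none. This tolerance replaced exact equality of length after a first correlation had been seen. The GC trend was a locally weighted regression with a span of 20% (statsmodels 0.14.6) on genes with at least 100 counts, and was removed by scaling library 2 per gene. Sequences shared between genes were searched with blastn 2.17.0 at 95% identity. The match had to cover 80% of the length for mitochondrial copies and 50% for other named genes. Members of the ribosomal protein, oxidative phosphorylation and replication histone lists were not searched, except those among the most abundant genes or the largest ratios. Of 271 named genes searched, 49 shared such a stretch with another gene.

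The test was checked on counts simulated with the real means and library sizes, with counting error as the only noise. Among 15550 tested genes, all 100 genes changed 3-fold and all 100 changed 8-fold were called in the right direction, and 4 of 15350 unchanged genes were called. With a GC trend added and removed, 90 of 91 genes changed 3-fold were recovered and 18 of 14939 unchanged genes were called. With the trend added and left in, 9268 of the 14939 (62%) were called. The added trend was a straight line, capped at both ends, with a slope chosen to resemble the data. The 62% called follows from that choice and is no separate evidence on the cause. The few calls among unchanged genes follow from noise limited to counting error and from a trend set by the same GC value that was then fitted. They do not show how many calls in the real libraries are false, with or without the trend removed.

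The group, tests, 37 gene lists, named-gene rule and the other settings listed here were fixed before the data were examined. The rule named the 20 nuclear and 3 mitochondrial genes of highest mean TPM, the 3 most abundant members of each list and members under TPM 1 in both libraries, and the 10 largest ratios each way among called genes of mean TPM 1 or more. It also named all genes of the sex lists and the isoforms of 6 genes. A few further list members were named as examples after their values were seen. Some genes that the rule selects are not reported here. These settings were DESeq2 1.42.0 size factors, total counts, other count filters and ratio limits, the edgeR exact test with an assumed coefficient of variation of 0.1, posterior mean counts, credibility intervals, and other units, pseudocounts and thresholds. Figures were drawn with matplotlib 3.10.9.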

Results

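The study measured polyadenylated RNA in the kidney of an adult female C57BL/6J mouse, a common inbred strain, at 10 weeks of age. There was 1 group with 2 libraries, labelled technical replicates 1 and 2 of 1 biological replicate and called library 1 and library 2 here. The labels date the work on technical replicate 2 to May 2015. Library 1 held 28263730 expected counts and library 2 held 20720537. The labels name no treatment or second tissue, so the values themselves and the agreement of the 2 libraries are the results. With n = 2 libraries of 1 tissue sample, every SD is technical and says nothing about differences between animals. Levels are in TPM, a length-corrected share of each library.

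Genes of the proximal tubule, the thick ascending limb and the connecting tubule were abundant in the kidney. Miox, the first enzyme of inositol breakdown in the proximal tubule, had 63.5 TPM in library 1 and 2196 TPM in library 2. Umod, which encodes the urinary protein uromodulin of the thick ascending limb, stood at 1508 ± 1595 TPM (SD, n = 2 libraries; 381 and 2636 TPM). Of 77 markers of 10 epithelial cell types fixed before the data were examined, 69 reached TPM 1 in both libraries. Another 6 reached it only in library 2 and 1, Slc7a13 (1.03 and 0.81 TPM), only in library 1. Epha7, a thin limb marker, was under TPM 1 in both (0.78 and 0.98). Here and below, paired values are library 1 first.

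The general proximal tubule list had a median of 57.8 TPM in library 1 and 691 TPM in library 2, or 227 and 1089 with mitochondrial genes and their nuclear copies left out of the sum. Its abundant members included Miox and the fatty acid transporter and ligase Slc27a2 (457 and 1511 TPM). In the early proximal tubule list the phosphate transporter Slc34a1 stood at 93.5 and 1337 TPM, the lactate transporter Slc5a12 at 128 and 129 TPM, and the glucose transporter Slc5a2 at 6.67 and 225 TPM. The late proximal tubule was represented by Slc6a18 (103 and 310.2 TPM), Atp11a (28.2 and 113 TPM) and the organic anion transporter Slc22a7 (2.3 and 137 TPM). In the thick ascending limb, the sodium-potassium-chloride cotransporter Slc12a1 reached 400 and 568 TPM, and Egf, the precursor of epidermal growth factor, 217 and 719 TPM.

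Genes of the distal segments were also present. The thiazide-sensitive cotransporter Slc12a3 of the distal convoluted tubule had 3.98 TPM in library 1 and 261 TPM in library 2, Emx1 0.09 and 30.7 TPM, and the calcium-binding protein Pvalb 2.81 and 23.5 TPM. Connecting tubule genes were abundant, with the kallikrein Klk1 at 217 and 4721 TPM and 2 calcium-binding proteins, S100g at 623 and 1605 TPM and Calb1 at 193 and 124 TPM. Aqp2, the vasopressin-regulated water channel of principal cells, had 0.79 and 176 TPM. The other leading principal cell genes were the cortisol-inactivating enzyme Hsd11b2 (9.6 and 112 TPM) and the water channel Aqp3 (10.7 and 65.9 TPM). Intercalated cell genes included the ammonia transporter Rhcg (5.09 and 96.9 TPM) and the proton pump subunits Atp6v1b1 (5.59 and 82.5 TPM) and Atp6v1g3 (19.6 and 41.7 TPM). In the thin limb list the urea transporter Slc14a2 had 0.24 and 23.7 TPM and Bst1 7.51 and 10.8 TPM. Podocyte genes were present too, among them Podxl (23.2 and 85 TPM) and Synpo (9.47 and 26 TPM), with a list median of 4 and 11.3 TPM.

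**Figure D1:**
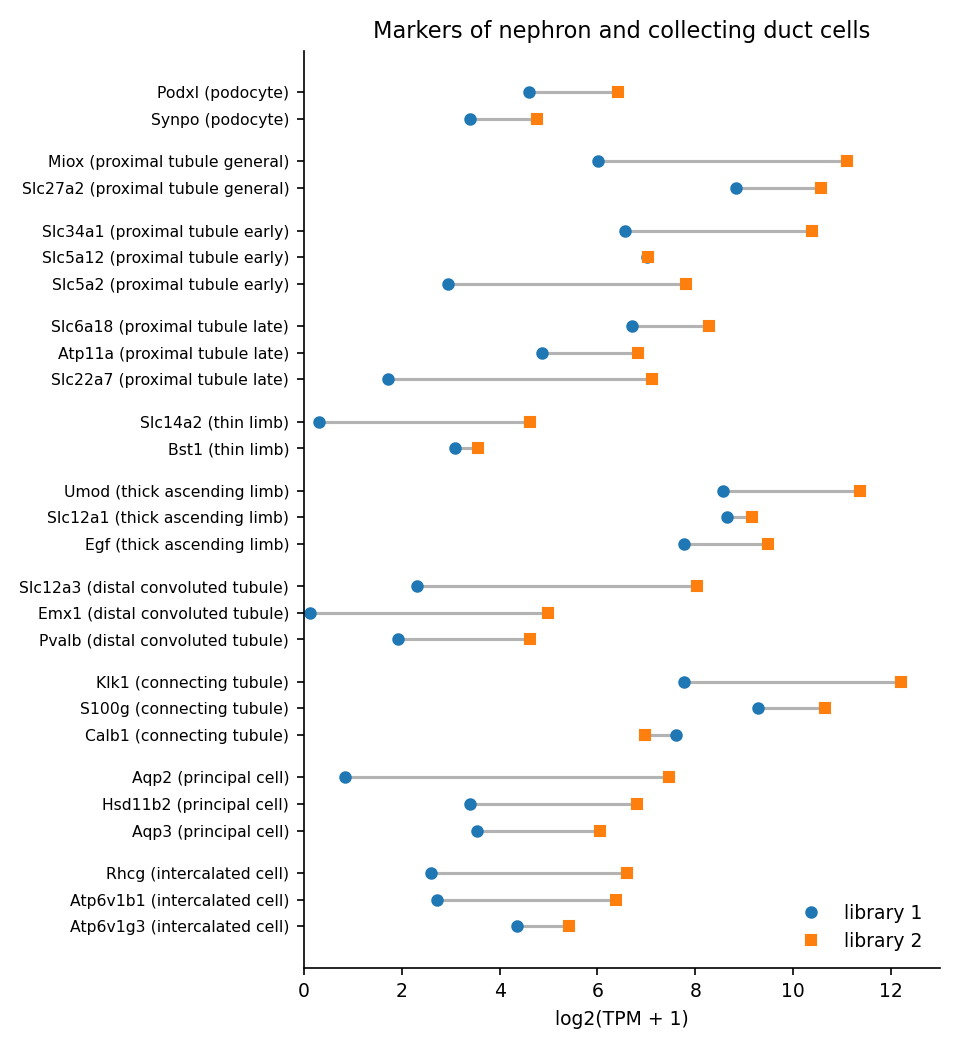
TPM of abundant markers, at most 3 from each of 10 epithelial lists, on a log2(TPM + 1) axis, with circles for library 1, squares for library 2 and a line joining the 2 values. Aqp2 (0.79 and 176 TPM) and Slc12a3 (3.98 and 261 TPM) lie far apart, while the values of Slc5a12 (128 and 129 TPM) nearly coincide.

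Cells outside the tubules were also represented. All 10 endothelial markers reached TPM 1 in both libraries, with Emcn at 71.9 and 72.9 TPM, Plvap at 1.79 and 103 TPM and Eng at 1.75 and 60.3 TPM. Stromal and mural genes were led by Dcn (46.2 and 65.5 TPM), Acta2 (2.71 and 60.6 TPM) and Tagln (3.58 and 55 TPM). Ren1, the renin gene of juxtaglomerular cells, had 0.51 and 91.4 TPM, and Akr1b7 0.92 and 4.68 TPM. Leukocyte genes were low, with Lyz2 at 5.31 and 23.8 TPM, Csf1r at 0.75 and 18.1 TPM and C1qb at 0.14 and 17.6 TPM, while the lymphocyte genes Cd79a and Cd3e stayed under TPM 1 in both. Urothelial genes reached at most a few TPM (Upk3a 0.07 and 4.85, Upk1a 0 and 4.84, Upk1b 1.4 and 2.39), and Krt20 stayed under TPM 1.

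Markers of neighbouring or other organs were scarce. All 9 adrenal genes (led by Star, Cyp21a1 and Cyp11a1, with Cyp11b1, Cyp11b2, Th, Dbh, Pnmt and Chga) and all 6 pancreatic genes (Cela2a, Ctrb1, Pnlip, Prss2, Cpa1 and Cel) were under TPM 1 in both libraries. Of 6 skeletal muscle genes, Mylpf reached 1.27 TPM in library 2 and Tnni2, Ckm, Acta1, Myh4 and Tnnt3 stayed under TPM 1. Fat genes were low but measurable, with Fabp4 at 23 and 72.7 TPM, Car3 at 15.9 and 23.7 TPM and Cfd at 0.09 and 25 TPM, and Lep was under TPM 1. Endothelial cells also express Fabp4. Liver genes were led by Ttr (2.49 and 31.6 TPM), Serpina1a (2.18 and 10.5 TPM) and Alb (3.55 and 7.05 TPM), with Ahsg under TPM 1. Globin genes of red blood cells separated the libraries, with Hba-a2 at 10.1 and 931 TPM, Hbb-bs at 29.8 and 868 TPM and Hba-a1 at 0.65 and 436 TPM.

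None of the Y-linked genes examined was detected. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 0 counts in both libraries. Xist, the RNA of the inactive X chromosome, had 85.2 ± 15.7 TPM (SD, n = 2 libraries). It was called higher in library 1 on TMM-scaled counts (log2 ratio -1.91). Genes known to be higher in female kidney were abundant, with Slc7a12 at 921 and 469 TPM, Hao2 at 442 and 680.5 TPM, Cyp4a14 at 273 and 460 TPM, Prlr at 101 and 77.3 TPM, Cyp2a4 at 36.3 and 116 TPM and Slc22a7 at 2.3 and 137 TPM. Genes known to be higher in male kidney had a median of 2.29 and 3.35 TPM, or 8.99 and 5.28, in the other direction, with mitochondrial genes and copies left out of the sum. Slco1a1 (0.01 and 0 TPM) and Cyp2j13 (0.27 and 0.3 TPM) were under TPM 1, and Acsm3, Cyp4a12a, Cyp7b1 and Slc7a13 lay between 0.81 and 3.78 TPM. Cyp2e1 (33.5 and 60.6 TPM), Odc1 (64.1 and 204 TPM) and above all Kap, an androgen-responsive kidney gene, were higher. Kap had 24788 ± 1246 TPM (SD, n = 2 libraries). Despite the similar TPM, it was called higher in library 1 on TMM-scaled counts (log2 ratio -1.46).

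Genes of kidney metabolism were measured next. Gluconeogenesis was represented by Pck1 (246 and 1177 TPM), Fbp1 (150.4 and 808 TPM) and G6pc (135 and 300 TPM). All 10 genes of fatty acid oxidation reached TPM 1 in both libraries, led by Acadm (316 and 759 TPM), Ehhadh (164 and 350.3 TPM) and Acadl (142 and 203 TPM). Of the vitamin D genes, the receptor Vdr had 20.5 and 87.1 TPM and the inactivating enzyme Cyp24a1 11 and 31 TPM, while the activating enzyme Cyp27b1 was under TPM 1 (0.15 and 0.84). Among tubule injury genes, Spp1 was high (1014 and 1868 TPM), Clu stood at 66.6 and 202 TPM and Vcam1 at 4.74 and 5.93 TPM, Havcr1 at 2.04 and 1.87 TPM, and Sox9 was under TPM 1. Immediate early genes were led by Zfp36 (11.3 and 53.7 TPM), Dusp1 (9.27 and 40.6 TPM) and Egr1 (8.68 and 35.4 TPM), with Fosb under TPM 1. Heat shock genes were led by Hsp90aa1 (448 and 226 TPM), Hsph1 (34.2 and 52.8 TPM) and Hspa1b (4.47 and 33.5 TPM).

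Mitochondrially encoded transcripts took 51.7% of TPM in library 1 and 19.8% in library 2. Before adding nuclear copies, mt-Atp8 (156936 and 77227 TPM), mt-Co1 (79325 and 37856 TPM) and mt-Cytb (42470 and 19092 TPM) had the highest mean TPM. The short mt-Atp8, at positions 7766 to 7969, had far fewer expected counts (171292 and 48817) than mt-Co1 (3313022 and 843917). Its TPM thus rests on a very small effective length and is uncertain. Summed with their copies, mt-Atp6 (91409 and 34392 TPM), mt-Co2 (89751 and 43442 TPM) and mt-Co3 (75299 and 39889 TPM) exceeded mt-Cytb. The ribosomal RNAs mt-Rnr2 and mt-Rnr1 had 1924 and 995 TPM and 1589 and 1056 TPM. Of the 20 most abundant nuclear genes, 6 were unprocessed pseudogenes on chromosome 1 that copy mitochondrial genes: Gm28661 (49062 and 41936 TPM), Gm10925, Gm28437, Gm10222, Gm28438 and Gm29216. With Gm28439 they filled positions 24611535 to 24616197 of mm10, and each matched a mitochondrial transcript at 99.7% to 100% identity. Reads of such sequences cannot be assigned with certainty. The 2 members of a pair were split differently in each library: mt-Co2 had 40689 and 1506 TPM, while its copy Gm28661 went from 49062 to 41936 TPM (log2 ratio -1.59 on TMM-scaled counts). Together mitochondrial genes and their 10 copies took 74.5% of TPM and 46.8% of expected counts in library 1, against 36.5% and 15.7% in library 2.

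**Figure D2:**
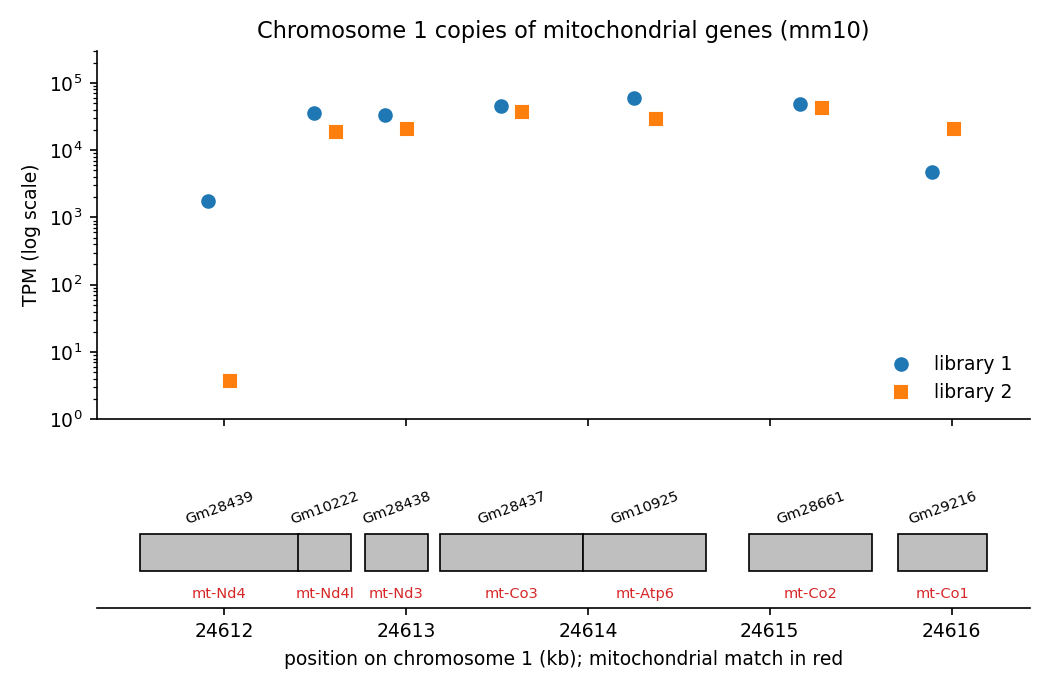
TPM of 7 chromosome 1 pseudogenes (log axis; circles, library 1; squares, library 2) above a map of the genes on mm10 in kilobases, each with the mitochondrial gene it matches in red. Gm28439 had 1729 TPM in library 1 and 3.72 TPM in library 2, while Gm28661 was at 49062 and 41936 TPM.

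After Kap, the leading nuclear genes outside these copies included Gpx3, the secreted glutathione peroxidase made by the proximal tubule (2855 and 20021 TPM), the ferritin heavy chain Fth1 (964 and 5199 TPM), the translation factor Eef1a1 (1022 and 5020 TPM) and Klk1. They were followed by Tpt1 (2686 and 2063 TPM), the ferritin light chain Ftl1 (2.62 and 3589 TPM), the protease Napsa (117 and 3401 TPM), Cltrn (1878 and 1578 TPM), Aadat (1666 and 1446 TPM), Umod, the sodium pump regulator Fxyd2 (83.5 and 2915 TPM) and the ATP synthase subunit Atp5b (426 and 2460 TPM). Eef1a1, Tpt1 and Ftl1 share near-identical stretches with pseudogenes, so their counts are less certain.

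The second question was how well repeat libraries of the same kidney agree. Aqp2, Ren1 and Ftl1 differed by far more than counting error. Slc5a12 and Emcn had similar TPM but were called higher in library 1 on TMM-scaled counts (log2 ratio -1.51 and -1.44). TPM of 1 or more was reached by 9532 genes in library 1 and 13223 in library 2, of which 9379 were shared. The 3844 genes reached only in library 2 had a median transcript GC content of 55.8%, the 153 reached only in library 1 had 41.5%, and the shared genes 47.9%. At least 10 TPM in library 2 with 0 counts in library 1 was seen for 95 genes, and the reverse for 11. Across 13376 genes, which are not independent replicates, log2(TPM + 1) correlated with Pearson r = 0.682 and Spearman rho = 0.619. Within GC classes r fell from 0.963 below 40% GC (644 genes) to 0.402 at 60% or more (481 genes). For genes with 1000 to 10000 counts the SD of the log2 ratio between the libraries was 2.17, against a median counting error of 0.069, so the 2 libraries differed far beyond sampling noise.

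**Figure D3:**
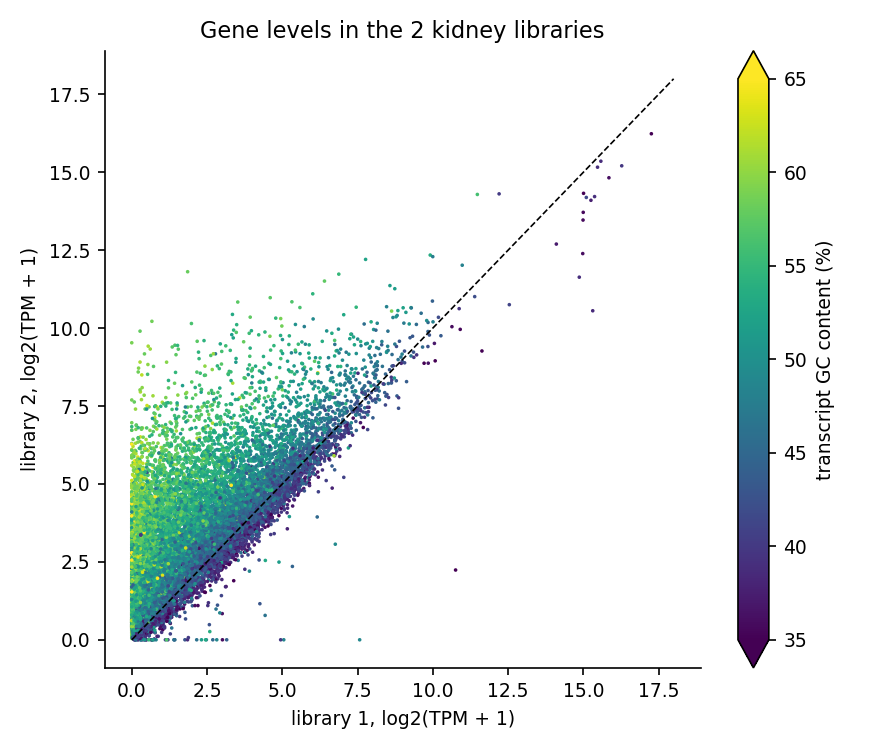
log2(TPM + 1) of each tested gene with a GC value in library 1 (x) and library 2 (y), coloured by the GC content of its transcript in percent, with the line of equality dashed. GC-rich genes lie above the line and AT-rich genes near or below it, as for Aqp2 (0.79 and 176 TPM) and Calb1 (193 and 124 TPM).

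The library ratio followed GC content closely. For the water channel Aqp2 (63.2% GC) the log2 ratio of library 2 over library 1 was 6.41 with a counting error of 0.262, for Umod (51.5% GC) 1.43, and for Calb1 (36.8% GC) -2, all relative to the typical gene after TMM scaling. Across 11508 genes with at least 100 counts the ratio correlated with transcript GC content at rho = 0.906 and with transcript length at rho = -0.284. The median log2 ratio was -1.9 for 620 genes below 40% GC, -0.47 for 3078 genes between 45% and 50%, 1.13 for 3107 genes between 50% and 55%, and 5.76 for 364 genes at 60% or more. Removing a smooth GC trend took away 73.7% of the variance across genes and lowered the SD from 2.41 to 1.24. The ratio left over still correlated with transcript length at rho = -0.242.

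**Figure D4:**
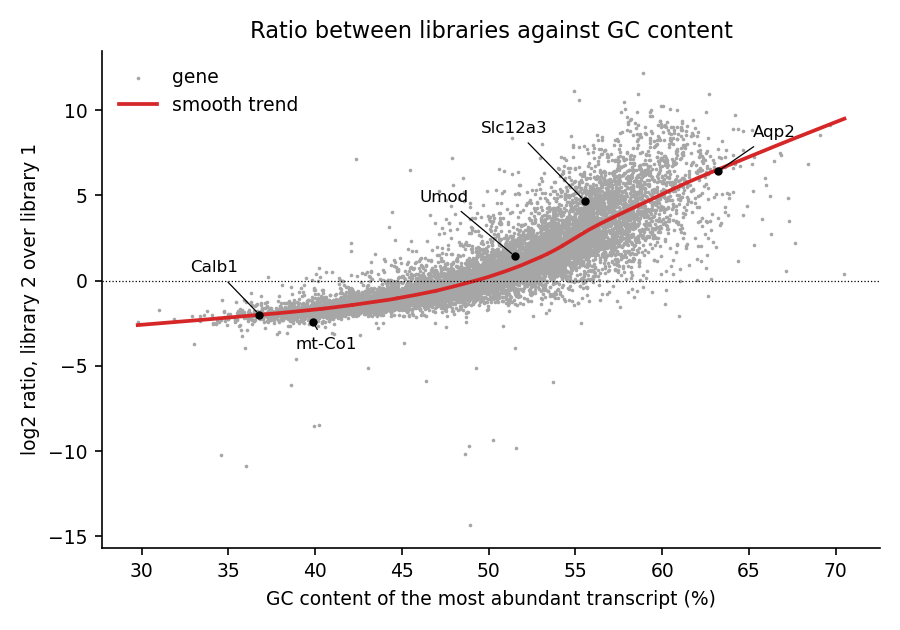
log2 ratio of library 2 over library 1 (TMM-scaled counts) against GC content in percent for genes with at least 100 counts, with the smooth trend in red and 5 genes named. The trend passes from -1.7 at 40% GC to 0.22 at 50% and 5.07 at 60%.

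Many genes differed between the libraries by more than counting error, among them genes of energy metabolism, translation and blood. The largest differences upward in library 2 were genes with next to no counts in library 1. Uqcr11, a subunit of respiratory complex III, had 0 counts in library 1 and 3118 in library 2, at least 758-fold higher against a floor of 3 counts. Tmem205 (at least 330-fold; 1360 counts), the methyl-CpG-binding protein Mbd3 (at least 321-fold; 1321 counts), Osgin1 (at least 203-fold), the autophagy gene Atg2a (at least 198-fold) and Tbc1d10a (at least 180-fold) were also at 0 in library 1. The ribosomal protein gene Rps15 had 2 and 4880 counts, a ratio of 1779 with an exact 95% interval of 492 to 14700. Of the 10 largest such ratios, 4 belonged to genes with near-identical stretches elsewhere: Rps15 itself, Gm20390 (a stretch shared with Nme2), Gm10359 (with Gapdh) and Rpl27-ps3 (with Rpl27).

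The largest ratios toward library 1 carried less certainty. Hsd3b4, of the 3-beta-hydroxysteroid dehydrogenase family, had 7610 counts in library 1 and 0 in library 2, at least 3480-fold lower in library 2, and an identical transcript, Gm10681, went from 64.1 to 1255 TPM. Gm14440, Gm28439, Gm28037, Gm20547, the histone gene Hist2h3c1, Gm29397 and Gm2004 likewise each shared a stretch of at least 95% identity with another gene. All 8 of these 10 genes that could be searched did so. The other 2, ENSMUSG00000103480.1 and ENSMUSG00000103578.1, had no name or sequence in the reference and were at 0 in library 2 (559 and 448 counts in library 1).

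Of 15553 genes tested with a two-sided exact binomial test on counts, 12986 (83.5%) passed the adjusted threshold and 9403 also differed at least 2-fold. Of the 9403, 5523 were higher in library 2 (median GC content 55.5%) and 3880 in library 1 (42.7%). This test compares 2 libraries, not conditions, and has no replicate check. The split depends on scaling, since total counts, which move the median log2 ratio of all genes by 0.9, gave 7648 higher in library 2 and 708 in library 1 and turned the median ratio of podocyte (-0.21 to 0.69), thin limb (-0.67 to 0.24), female-high (-0.68 to 0.23) and tubule injury genes (-0.6 to 0.3). With the GC trend removed, an alternative chosen after seeing the data, 3349 genes were called, 1867 of them called before in the same direction and 609 in the other.

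Gene groups differed in the same manner. Genes of cytosolic ribosomal proteins lay above all 10000 matched random lists, with 53 of 78 members called higher in library 2, 1 called higher in library 1 and 24 not called, and a median log2 ratio of 2.59. Its leading members were Rps24 (1028 and 1176 TPM), Rplp1 (10.5 and 1828 TPM) and Rps29 (9.16 and 1388 TPM), and Rpl39l and Rpl10l were under TPM 1. These members were not searched for sequences shared with other genes, so how certain their counts are is not known. Nuclear genes of oxidative phosphorylation also lay above all random lists, and 45 of 78 were called higher in library 2 and 5 higher in library 1, with a median of 1.78 (1.65 with 3 members at 0 in a library set at their bound). Atp5b, Ndufa4 (782 and 1425 TPM) and Cox6c (450 and 1357 TPM) led this list, and Cox7b2 and Cox8c had 0 counts. Erythroid genes were called higher in library 2 in 5 of 5 compared members, with a median of 5.13. Genes of mitochondrial messenger RNAs were called higher in library 1 in 13 of 13, with a median of -2.77.

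Among 31 lists with at least 3 members compared, 10 lay above the central 95% of random lists matched on expression and 2 below it. The 10 were ribosomal proteins, oxidative phosphorylation, erythroid, general proximal tubule (median log2 ratio 0.61), early proximal tubule (1.34), stroma (2.17), gluconeogenesis (1), fatty acid oxidation (0.53), urothelium (4.18, or 3.97 with 2 members at 0 set at their bound) and RNAs without a poly(A) tail (5.58, or 4.2 with 3 set at their bound). The last were led by Rn7sk (1.37 and 60.5 TPM) and the identical pair Rn7s1 and Rn7s2 (0.14 and 41.3 TPM each), with Terc at 0. The 2 below were mitochondrial messenger RNAs and genes higher in male kidney (median -1.43; 5 of 8 called higher in library 1 and none with total counts). Replication histone genes lay within the range, with 47 of 64 under TPM 1 in both libraries and Hist1h2bc (155 and 363 TPM), Hist1h1c (16.9 and 122 TPM) and Hist2h2aa2 (0 and 105 TPM) leading.

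Of the 77 epithelial markers, 34 were called higher in library 2, among them Slc12a3, Aqp2, Miox and Umod, 12 higher in library 1, among them Calb1 and Atp6v0d2, and 31 were not called, among them Slc12a1 and Egf. With total counts the split was 42 and 1. Endothelial genes were split 5 to 1 with 4 not called, leukocyte genes 4 to 1 of 7, and immediate early genes 8 to 0 of 12. Calls adjusted over the list alone had the same counts in each of the 37 lists as those over all genes. With the GC trend removed, ribosomal proteins (1.59), oxidative phosphorylation (0.61), erythroid (2.52) and early proximal tubule (0.91) stayed above the range of random lists, and distal convoluted tubule (1.78) and leukocyte genes (1.06) came to lie above it. General proximal tubule (0.16), stroma (0.31), gluconeogenesis (0.21), fatty acid oxidation (0.24), urothelium (0.67), RNAs without a poly(A) tail (0.32) and male-high genes (-0.19) no longer lay outside it. Podocyte (-0.65) and mitochondrial (-0.77) genes lay below it, as did immediate early (-0.7) and heat shock genes (-1.52), whose medians had been positive. Members without a GC value dropped out, which left 4 of 6 distal convoluted tubule genes. It also left 4 of 6 heat shock genes, among them the near-identical Hspa1a and Hspa1b. The ratio left over still correlated with transcript length (rho = -0.242), and the random lists were not matched on length, so a length trend may enter these ranks.

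The third question was which transcript of a gene dominates. Slc12a1, whose splice forms differ along the thick ascending limb, was 85.8% Slc12a1-201 in library 1 and 22.7% in library 2, where Slc12a1-203 took 65%. These 2 forms are 4645 and 4642 bases long with 45.4% and 45.6% GC. Umod had 1 annotated transcript. Slc4a4, the sodium bicarbonate cotransporter, was led by Slc4a4-207 in both (86.7% and 58.3%) and Wnk1 by Wnk1-208, annotated as a retained intron (35.1% and 29.4%). Fgfr2 was led by Fgfr2-217 (62.5% and 36.1%). Slc4a1 changed from Slc4a1-201 alone in library 1 to 55.1% of the short Slc4a1-204 in library 2. Slc4a1-204 is annotated as a processed transcript of 357 bases, not as protein-coding. Its share may rest on a small effective length and is uncertain. Of 2688 genes with at least 2 transcripts and TPM of 10 in both libraries, 1862 (69.3%) had the same most abundant transcript.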

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

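Removing the GC trend, leaving out mitochondrial genes with their copies, equal-length GC matching and list tests with total counts were chosen after seeing the data. The count of 9403 called genes stayed between 7569 and 12986 under every setting fixed before the data were examined, and fell to 3349 of 14801 genes tested with the GC trend removed (8952 of the 9403 have a GC value) and to 2567 of 11425 with the trend from transcripts of equal length. The direction split moved more: 708 genes were called higher in library 1 with total counts, 116 with TPM intervals that do not overlap (8287 higher in library 2), 6097 with no limit on the ratio and 1550 with the GC trend removed (1799 higher in library 2). Pearson r of 0.682 became 0.631 with a pseudocount of 0.1, 0.855 with no filter and 0.534 at TPM of 10 or more; Spearman rho of 0.619 became 0.901 and 0.437 in the last 2. A correlation was taken as moved when it shifted by 0.05 or more. Genes detected in both libraries numbered 5375 at TPM 5 and 3530 at TPM 10, and single libraries gave 9532 to 13223. The same main transcript was shared by 66.9% of genes at TPM 1 and by 74.4% where the top transcript held 60% or more. Lists outside the range of random lists numbered 12, against 11 with DESeq2 size factors or total counts and 14 with centred log2(TPM + 1) ratios. With only members of 100 or more counts they numbered 9, and some lists were then too small to compare. The causes were not tested, except that a filter changes which genes enter. With the GC trend removed, these log2 ratios changed sign and stayed called: Gpx3 (-1.08), Hsd11b2 (-1.82), Avpr2 (-1.23), Aqp6 (-1.47), Col1a1 (-1.84), Jun (-1.46), Hspa1b (-2.62), Hspa1a (-3.07), Clu (-1.02), Hist1h1c (-1.05), Rpl35 (-1.9) and Ndufb9 (-1.62). The medians of immediate early (-0.7) and heat shock genes (-1.52) changed sign and fell below the range of random lists. Those of thin limb, principal cell, intercalated cell, endothelial, adrenal, female-high and vitamin D genes changed sign within it. Of 413 tested list members and named genes, none changed sign while called under the other alternatives checked. The GC trend from transcripts of equal length and the other ratio limits were not checked for this. With mitochondrial genes and their copies left out of the TPM sum, chosen after seeing the data, the level of 14 of 35 lists moved by more than its SD between the libraries, and of 6 with only mitochondrially encoded genes left out, since the total shrinks most in library 1. The 6 are connecting tubule, liver, male-high, female-high and tubule injury genes and Xist. Without the copies too, medians of liver, male-high, female-high and tubule injury genes became higher in library 1. Named genes removed by a filter or without a GC value got no value there. Genes under 10 counts were not tested.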

Other observations

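Ftl1, Klk1 and Fxyd2 held very different ranks in the 2 libraries. Ftl1 ranked 7265 in library 1 and 21 in library 2, Klk1 176 and 19, and Fxyd2 522 and 24. Aqp2 was under Aqp4 in library 1 (0.79 against 22.9 TPM) and above it in library 2 (176 against 20.3 TPM). The count-weighted GC content outside mitochondrial genes and copies was 45.3% in library 1 and 49.8% in library 2.

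The first pattern is the large number of genes that differ between repeat libraries, where the GC and length correlations were fixed before the data were examined. The removal of the GC trend, the omission of mitochondrial copies and the window test were chosen after the pattern was seen, with predictions written before their results. For transcript length as the main cause, rho was -0.284, within the bound set beforehand for arguing against it. Among protein-coding nuclear genes, a setting also fixed beforehand, rho was -0.304, past that bound, so the verdict depends on the genes used. With mitochondrial genes and copies omitted, 9390 genes were called. This cannot decide on mitochondrial reads, since TMM scaling already takes up their share and the median log2 ratio moved by only -0.01. GC content may be the main cause (rho = 0.906). Once the trend was removed, 22.6% of tested genes were called, 1867 of them called before in the same direction. A trend on the mean GC content of the chosen transcript thus did not take up the whole difference. It leaves GC content along the transcript and in other transcripts of the gene in place, so it cannot decide whether GC content is the whole cause. Both libraries are labelled technical replicates of 1 biological replicate, so a difference between animals or conditions is not the cause. No other biological explanation was tested. Uneven GC content along the transcript stays open. The ratio left over correlated with the GC content of the most AT-rich 200-base window at rho = 0.192, between the bounds set beforehand. Removing that trend too lowered the SD only from 1.22 to 1.14 and left ribosomal protein genes at a median of 1.13.

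The second pattern is the rank of nuclear pseudogenes among the most abundant genes, and its test was chosen after the pattern was seen. Of the 7 nuclear genes without a protein product among the 100 most abundant, 7 matched a mitochondrial transcript, so reads shared with near-identical mitochondrial sequences may account for their rank. Expression from chromosome 1 itself was not tested, nor was any biological explanation.

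The third pattern is the change of main transcript between libraries, seen in 826 genes, and its test was chosen after the pattern was seen. Among 757 of them with GC values, library 1 had the lower-GC transcript in 81.5% (exact 95% interval 78.6% to 84.2%). The interval treats genes as independent, which genes measured in the same libraries are not. The top transcripts held 60% or more in both libraries in 270 of the changes. GC content may thus shift isoform shares as well as gene levels. The 2 main forms of Slc12a1 hardly differ in GC content (45.4% and 45.6%). Both libraries are of 1 biological replicate, so a difference in splicing between animals or conditions is not the cause. No other biological explanation was tested.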
